A study of Mus musculus with 4 samples.

How the data were processed

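Single-cell ATAC-seq, which marks open chromatin by where the Tn5 transposase inserts sequencing adapters, was run on nuclei of 4 sorted mouse populations of the C57BL/6 strain, with 1 library for each. Per the labels' protocols, libraries were made with the 10x Genomics single-cell ATAC kit and sequenced on a NovaSeq instrument. Cutadapt, BWA, Cell Ranger ATAC, Cell Ranger, MACS2 and R 3.6.0, and the mouse builds mm10 and GRCm38.p5, are named in the submitters' processing notes; their order, their settings and the filters on cells and peaks are not given in the sources used here. The deposited matrix held 198127 peaks, shared by all libraries, and 8822 cells, and its values were 0 or 1. Per the file headers each column was a cell whose name began with its library, and a value of 1 was read as a cell with at least some signal in that peak. The authors' binarization removes the number of fragments, so a peak that is open in most cells cannot show a further gain, and no correction for depth was built into the values. No doublet caller was run; 3 fetal liver cells and 6 megakaryocyte progenitor cells, and no cell of the other libraries, had over 2 times the median number of open peaks of their library.

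An open call is a cell and peak pair with the value 1. Calls were summed over the cells of a library and given per 1000000 open calls of that library, which takes out depth to a first approximation. Gene accessibility was the sum over peaks overlapping a gene and 2 kb on either side, with genes from a RefSeq table of GRCm38.p6, the assembly that mm10 names; all 305 genes of the fixed lists were found in it. The table gives neither strand nor exons, so the planned window of 2 kb upstream was replaced by 2 kb on both sides, promoters could not be told from the other end of a gene, and peaks are placed only inside or outside genes. The motif analysis and the promoter alternatives were not run, since no genome sequence or transcription start sites were used here. Coordinates are those of the deposited peak names; whether their starts count from 0 or 1 is not given in the sources used here.

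Log2 ratios used a pseudocount of 1 on that scale. Folds of single genes are given without the pseudocount, with exact conditional 95% intervals, while genes were ranked on the log2 ratio. Shares have exact Clopper-Pearson intervals, and a share of 0 has the limit that 3 cells would give. List medians have 95% ranges from 1000 Poisson resamplings of the calls and a percentile among 10000 random lists of the same size matched on accessibility in 10 bins, as a description of these libraries. All of these cover counting error only, and intervals on calls treat the calls of a cell as independent. Cells are not replicates and each population was 1 library, so no test, p-value or count of changed genes was made, and a ratio describes a pair of libraries. A gene entered a comparison with at least 0.05 calls per cell in either library, and a peak when open in at least 5% of the cells of either library. Peaks of chromosomes 1 to 19 and X with a log2 ratio of at least 1 or at most -1 were counted as higher or lower, and list members with at least 0.5 or at most -0.5.

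The gene lists, the rules for naming genes and the main settings were fixed before the data were examined. There were 16 lists, namely megakaryocyte and platelet genes, megakaryocyte and erythroid transcription factors, erythroid, mast cell and basophil, granulocyte and monocyte, lymphoid, stem cell, fetal programme, antigen presentation, interferon response, immediate early, proliferation, hepatocyte, macrophage, endothelial and housekeeping genes. Named genes were the 8 autosomal protein-coding genes with the highest and the 8 with the lowest log2 ratio among those with at least 2 peaks, the 4 megakaryocyte list members and the 2 members of every other list with the largest absolute log2 ratio, and a fixed set of 21 genes, of which 1 is not reported here. Named peaks were the 5 highest and the 5 lowest autosomal peaks, and peaks inside named genes are given as further detail, chosen after their values were seen. Genes that encode the surface proteins used for sorting (Itga2b, Kit, Ly6a, Cd48, Slamf1, Flt3 and Itgam) are given as values only.

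The cells of each library were split at random into 2 equal parts. Peaks typical of megakaryocyte progenitors were found on 1 part and measured on the other, which held 1202 FL CD41-, 1155 ABM CD41-, 562 ABM CD41int and 1493 MkP cells. Such MkP-high peaks had at least 2 times the rate of the mean of the 3 stem cell libraries and were open in at least 5% of MkP cells; HSC-high peaks were the reverse. Cells were clustered by TF-IDF weighting, truncated singular value decomposition with 30 components, 20 nearest neighbours and the Leiden method at resolution 1. The leading component was left out because its absolute correlation with the logarithm of open peaks per cell was 0.898. A cluster in which MkP cells made up over 50%, with libraries weighted equally, was called MkP-dominated. Clusters were read by the number of marker list members with a log2 ratio of at least 0.5 over the mean of the other clusters; this rule was chosen after the data were seen, in place of the list with the highest median, whose values are given with the alternatives. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used.

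The code was tested on libraries simulated from the openness of peaks in the adult CD41-negative library alone, with the cell number of each library. Changed genes were drawn from those without widely open peaks. Neither other differences between libraries nor the limit on the most open peaks was tested. Among 14879 genes, median log2 ratios of -0.91, -0.55, 0.55 and 0.95 were recovered for simulated folds of 0.5, 0.67, 1.5 and 2, and 0% of 14596 unchanged genes passed 0.5. Of 199 changed genes, 98.0% had an interval that held the simulated ratio. For peak sets, 94.9% of simulated peaks were recovered, and libraries simulated as equal gave folds of 0.996 and 1.00. Alternatives covered gene windows, median-centring, cells matched on depth, cells thinned to 10000 open peaks, cells without the deepest and shallowest 5%, pseudocounts of 0.1 and 5, other openness and size thresholds, other references for MkP-high peaks, 5 other random splits of the cells, and other cluster settings.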

Results

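The study asked how far haematopoietic stem cells (HSC) of the fetal liver and of the adult bone marrow are primed towards megakaryocytes, the cells that shed platelets. Open chromatin was profiled in 4 mouse libraries. Fetal liver (FL) HSC came from embryonic day E14.5, and all adult bone marrow (ABM) cells from animals aged 12 weeks. All HSC were lineage-negative, cKit-positive, Sca1-positive, CD48-negative, CD150-positive and Flt3-negative. CD41, the platelet integrin encoded by Itga2b, split them further: the FL CD41- HSC and ABM CD41- HSC libraries lacked it, and the ABM CD41int HSC library carried it. The ABM MkP library held megakaryocyte progenitors, sorted as cKit-positive, Sca1-negative cells with CD150 and CD41. Only the adult gates also removed CD11b-positive cells.

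The libraries held 2403 FL CD41-, 2310 ABM CD41-, 1123 ABM CD41int and 2986 ABM MkP cells. They gave 41585090, 38074302, 18779405 and 53566479 open calls, where a call is a peak scored as open in a cell. The median cell had 17067, 16423, 16816 and 17799 open peaks, so depth was close to equal. Each population was 1 library without replicates, and every interval below covers counting error only.

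The MkP library served as the reference for open chromatin along the megakaryocyte path. Compared with ABM CD41- HSC it was more open over platelet and erythroid genes and less open over stem cell genes. Of 32 measured megakaryocyte and platelet genes, 26 had a positive log2 ratio and 9 reached 0.5; the median was 0.25 (0.21 to 0.30), above all 10000 matched random lists. The 4 largest ratios in that list belonged to Gp6, the platelet collagen receptor (5.25-fold, 3.55 to 8.02), Treml1, a platelet receptor (2.42-fold, 2.17 to 2.71), Gp1bb, part of the von Willebrand factor receptor (1.96-fold, 1.82 to 2.13), and Rab27b, which acts in granule release (1.87-fold, 1.80 to 1.95). Gata1, the transcription factor of megakaryocytes and red cells (mm10, chromosome X, 7959260 to 7976663), was 3.0-fold higher (2.67 to 3.38), and a peak inside it (7971057 to 7971984) was open in 34.2% of MkP and 9.31% of ABM CD41- HSC. Pf4, platelet factor 4, was 1.35-fold higher (1.25 to 1.46), while Vwf (1.09-fold), Fli1 (1.08-fold) and Nfe2 (1.08-fold) differed little, and Itga2b was at 1.01-fold.

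Other lists also lay away from 0 in MkP, with medians of 0.21 (0.11 to 0.28) for macrophage and 0.19 (0.11 to 0.27) for endothelial genes; hepatocyte genes were at -0.26 (-0.40 to -0.19), 8 of 9 negative, within the central range of random lists. The list of megakaryocyte and erythroid transcription factors was at 0.10 (0.07 to 0.11), within the central range of random lists. The erythroid list had a median of 0.19 (0.15 to 0.25) in MkP, with 17 of 22 genes positive; Alas2, a haem synthesis enzyme, was at 2.75-fold, though at -0.24 (log2) when only peaks within 1 kb of gene ends were counted, and Epb42, a red cell membrane protein, at 0.439-fold. The stem cell list had a median of -0.19 (-0.26 to -0.13), with 4 of 23 genes at or below -0.5, among them Ndn (0.260-fold) and Robo4 (0.407-fold); Mecom and Hlf, regulators of HSC, were at 0.640-fold and 0.753-fold. The fetal programme list had a median of -0.20 in MkP, with the imprinted gene Peg3 at 0.438-fold and Sox17 at 0.550-fold. The mast cell and basophil list split, with Gzmb at 6.03-fold and Il4 at 0.319-fold, and its median turned from 0.14 to -0.06 with no minimum of calls per gene. Over all genes, Il1b, encoding interleukin-1 beta, had the highest ratio (13.8-fold, 11.1 to 17.3), followed by Ly6g6f (9.11-fold) and Apol9b (7.17-fold), and the lowest were Slco6d1 (0.0559-fold), Gbp8 (0.123-fold) and Mmp16 (0.168-fold). The peak inside Il1b at chromosome 2, 129368124 to 129368716, was open in 43.7% of MkP cells (41.9 to 45.5%) against 1.34% of ABM CD41- HSC, and a peak 24314 bases from Pde5a at chromosome 3, 122703766 to 122704844, in 45.8% against 0.823%. In all, 9368 of 83724 peaks were higher and 6834 lower in MkP. Of these, 5.55% and 6.83% lay within 1 kb of a gene end, against 19.9% of all peaks compared. The balance moved with the size threshold, with 15380 and 15166 at 1.5-fold and 1722 and 475 at 4-fold.

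**Figure D1:**
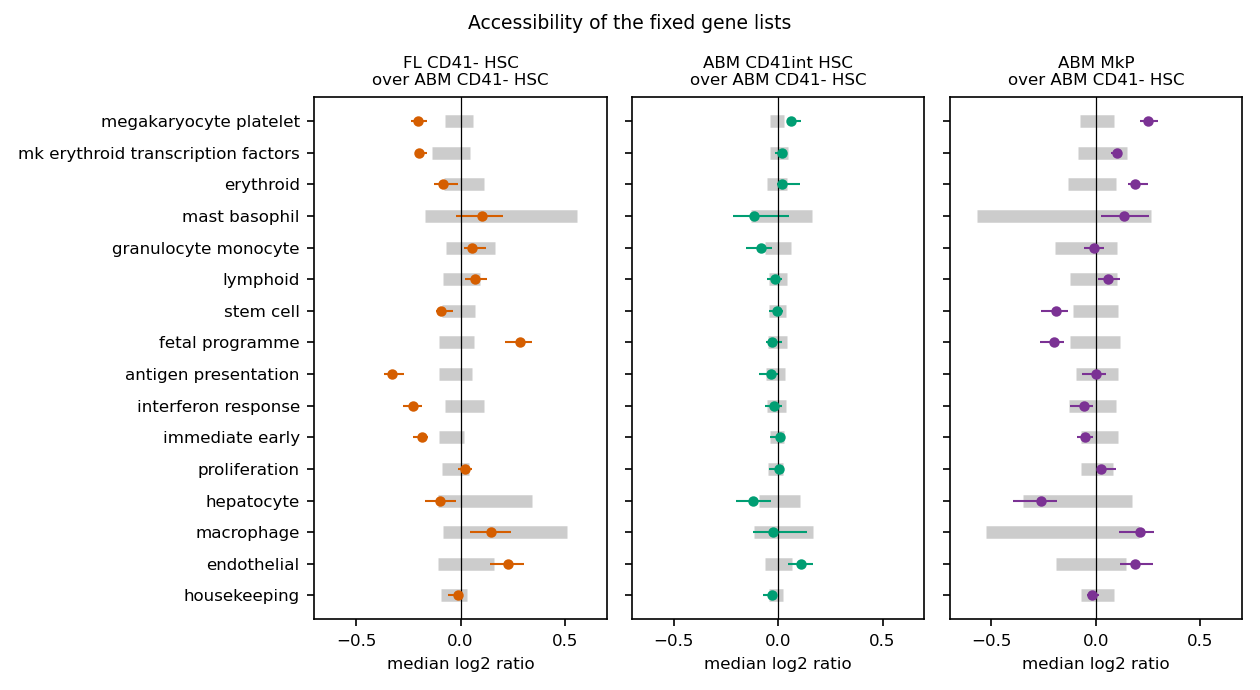
Median log2 ratio of accessibility for the 16 fixed gene lists (rows) in FL CD41- HSC, ABM CD41int HSC and ABM MkP over ABM CD41- HSC; points are medians, lines their 95% counting ranges, and grey bars the central 95% of 10000 matched random lists. The megakaryocyte list lies at -0.21, 0.06 and 0.25.

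The comparison of ABM CD41int with ABM CD41- HSC asked what CD41 marks among adult HSC. CD41int HSC were slightly more open over megakaryocyte genes and much more open at a small set of peaks, most of which were also higher in MkP. The megakaryocyte list had a median of 0.06 (0.04 to 0.11), or 0.13 when only peaks within 1 kb of gene ends were counted. In this list 26 of 31 genes were positive and none lay at or beyond 0.5 in either direction. Its largest ratios were Tubb1, platelet tubulin (1.38-fold, 1.19 to 1.60), Myl9, a myosin light chain (1.35-fold, 1.18 to 1.54), Rab27b (1.25-fold) and Treml1 (1.22-fold). The transcription factor list had a median of 0.02 (-0.02 to 0.04), with Gata1 at 1.41-fold (1.19 to 1.67) and Lmo2 at 0.865-fold, Gata2 at 0.943-fold, Fli1 at 0.959-fold and Nfe2 at 0.972-fold. Pf4 was at 1.15-fold (1.03 to 1.27), whereas Vwf (1.02-fold), Gp1bb (1.09-fold, 0.967 to 1.22) and Itga2b itself (0.980-fold, 0.924 to 1.04) were not distinguishable from equal at this depth.

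Among autosomal protein-coding genes with at least 2 peaks, Il1b again had the highest log2 ratio in CD41int HSC (2.82-fold, 2.12 to 3.76). Timd4, a phosphatidylserine receptor (2.44-fold, 1.95 to 3.06), followed on that scale, and Clec4a3 was lowest (0.445-fold, 0.301 to 0.642). Without the pseudocount, Slitrk1 (2.78-fold) lay above Timd4 and Gm52363 (0.438-fold) below Clec4a3. The granulocyte and monocyte list had a median of -0.08 (-0.15 to -0.03), with 14 of 17 genes negative, and the endothelial list 0.11 (0.05 to 0.17), which turned to -0.01 with gene ends only. Hepatocyte genes were at -0.12 (-0.20 to -0.04), with 8 of 9 negative, and housekeeping genes at -0.03, with 16 of 20 negative. The stem cell list was at -0.01 (-0.04 to 0.02). Only 306 of 74422 peaks were higher and 13 lower in CD41int HSC, and 193 of the 306 were also higher in MkP, where independent lists would share 30.2. At 1.5-fold, 2227 peaks were higher and 639 lower in CD41int HSC, and at 4-fold 0 and 0. None of the 306 lay in the window of a megakaryocyte list gene (0 of 32, median of random lists 0). With separate parts of the ABM CD41- cells (1155 each) as the controls, tried after the data were seen, 222 and 195 peaks were shared (37.5 and 33.5 for independent lists). These parts come from 1 library, so part of the excess may still come from it. The covariance of the 2 log2 ratios over peaks was 0.0420, against 0.00391 from the shared library in a simulation of equal libraries, and 0.0391 and 0.0372 with separate control cells. A peak 73078 bases from Rap1b (chromosome 10, 117919052 to 117919992) was open in 19.7% of CD41int HSC, 4.16% of ABM CD41- HSC and 45.8% of MkP.

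The comparison of FL CD41- with ABM CD41- HSC addressed megakaryocyte priming before and after birth. These libraries also differed in organ and in the CD11b gate, which cannot be told apart from age in this design. FL HSC were less open over megakaryocyte genes and their transcription factors, less open over antigen presentation and interferon genes, and more open over fetal programme genes. The megakaryocyte list had a median of -0.21 (-0.24 to -0.16), with 25 of 31 genes negative, below all 10000 random lists. Itgb3, the partner of CD41 in the platelet integrin (chromosome 11, 104608000 to 104670476; 0.682-fold, 0.652 to 0.714), Plek, a protein kinase C substrate of platelets (0.686-fold, 0.65 to 0.724), and Gp9, part of the von Willebrand factor receptor (0.691-fold, 0.642 to 0.743), lay at or below -0.5, and Treml1 was at 0.714-fold. With windows of 10 kb on either side, 1 list member lay at or below -0.5 and the list median was -0.14. Pf4 was at 0.891-fold (0.815 to 0.974), and Vwf (1.02-fold, 0.980 to 1.05), Selp (1.04-fold, 0.988 to 1.10) and Gp1bb (0.916-fold, 0.832 to 1.01) were close to equal.

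The list of megakaryocyte and erythroid transcription factors had a median of -0.20 (-0.22 to -0.16) in FL, with Gata1 at 0.663-fold (0.562 to 0.781), Lmo2 at 0.769-fold, Gata2 at 0.907-fold, Nfe2 at 0.897-fold and Fli1 at 0.941-fold. The Gata1 peak described above was open in 4.20% of FL HSC (3.44 to 5.08%). Against ABM CD41int HSC the megakaryocyte list had a median of -0.31 (-0.36 to -0.26) in FL, with 27 of 31 genes negative and 7 at or below -0.5.

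The fetal programme list had a median of 0.28 (0.21 to 0.34) in FL HSC, with 16 of 18 genes positive and 6 at or above 0.5. Lin28b, the RNA-binding repressor of let-7 (chromosome 10, 45376617 to 45486314), was 2.53-fold higher (2.38 to 2.70) and Igf2bp3, a fetal RNA-binding protein, 2.28-fold (2.15 to 2.43), whereas Hmga2 (1.12-fold) and Igf2bp2 (1.06-fold) differed less. A peak at 1 end of Igf2bp3 (chromosome 6, 49214808 to 49215954) was open in 65.0% of FL and 12.0% of ABM CD41- HSC. All 13 antigen presentation genes (median -0.33, -0.37 to -0.27; Tap2, a peptide transporter, 0.630-fold) and all 21 interferon response genes (median -0.23, -0.27 to -0.18; Ifi44 0.427-fold, Zbp1 0.554-fold) were negative in FL. Of 23 immediate early genes, which stress and tissue handling can induce, 22 were negative (median -0.18, -0.23 to -0.16; Btg2 0.656-fold).

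The stem cell list had a median of -0.09 in FL HSC, with Hlf at 0.772-fold, Mecom at 0.895-fold and Tek, an angiopoietin receptor, at 1.53-fold. The erythroid list was at -0.08, with Rhag at 0.611-fold and Slc4a1 at 1.74-fold. Slc4a1 turned to -0.32 (log2) with windows of 10 kb on either side. Both list medians lay just below the central range of random lists. Medians were 0.10 for the mast cell and basophil list, of which 5 genes were measured, 0.06 for granulocyte and monocyte genes, 0.07 for lymphoid genes (-0.02 with gene ends only) and 0.02 for proliferation genes, with Mpo, a neutrophil enzyme (2.12-fold, 1.87 to 2.40), Ltf (2.34-fold) and Il7r, the interleukin-7 receptor (2.68-fold, 2.14 to 3.37), higher in FL. Among markers of other cells of the tissue, hepatocyte genes had a median of -0.10, with Ahsg at 0.315-fold and Afp at 0.721-fold, macrophage genes 0.14 (median of random lists 0.15), with Marco at 6.57-fold (5.43 to 7.99), and endothelial genes 0.23 (0.14 to 0.30), with Plvap at 1.80-fold and Cdh5 at 1.63-fold. Housekeeping genes were at -0.01. The gate genes Slamf1 and Ly6a were at 0.685-fold and 0.695-fold, Itga2b at 0.767-fold, Itgam, whose product CD11b was gated only in the adult, at 1.17-fold, Cd48 at 1.06-fold, Flt3 at 1.10-fold and Kit at 0.975-fold.

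Among autosomal protein-coding genes with at least 2 peaks, the highest log2 ratio in FL was that of Cntnap5a (27.0-fold, 17.7 to 43.4). Gm46320 (24-fold, 15.9 to 38.2) and Pxdn, a matrix peroxidase (11.8-fold, 9.41 to 14.9), followed on that scale. The lowest were Ankrd65 (0.159-fold, 0.126 to 0.20), Gm4951 (0.195-fold) and Aldh1a1, a retinal dehydrogenase (0.219-fold, 0.192 to 0.248). Without the pseudocount, Fut9 (22.3-fold) lay above Pxdn and Fam180a (0.170-fold) below Gm4951. In all, 4468 of 82813 peaks were higher and 4615 lower, and 9.51% and 5.01% of these lay within 1 kb of a gene end. The balance depended on the setting, with 1642 higher and 2708 lower among peaks open in at least 10% of cells of 1 library, and 11383 and 9708 at 1.5-fold. With cells thinned to 10000 open peaks, 2203 were higher, while the count of lower peaks stayed within 1.5-fold. Peaks lower in FL lay in the windows of 6 of 32 megakaryocyte genes (median of random lists 5). For megakaryocyte and erythroid transcription factors these counts were 6 of 17 (6). Interferon genes had 7 of 21 (1) and immediate early genes 6 of 23 (2). The 5 highest peaks in FL all lay on chromosome 12, among them 21783660 to 21785064, open in 37.7% of FL and 1.77% of ABM CD41- HSC. A peak inside Col16a1 (chromosome 4, 130074812 to 130075997) was open in 2.83% of FL and 58.8% of ABM CD41- HSC. The FL library also differed from the adult libraries in having no call in 5 mitochondrial peaks; how each library was processed is not given in the sources used here, which limits every FL over ABM ratio. FL ratios ran with openness: peaks open in under 1% of cells had a median log2 ratio of 0.22, and those open in 16 to 32% of cells -0.08. Of the 4615 peaks lower in FL, 1347 were also lower in MkP (332 for independent lists) and 204 higher (455); of the 4468 higher in FL, 161 were also higher in MkP (441) and 144 lower (322). With separate control cells these were 1273 and 1256 shared lower peaks, and 221 and 228 in opposite directions; the covariance of the ratios was 0.0189, against 0.00391 in the simulation. Part of the excess may come from the shared library.

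**Figure D2:**
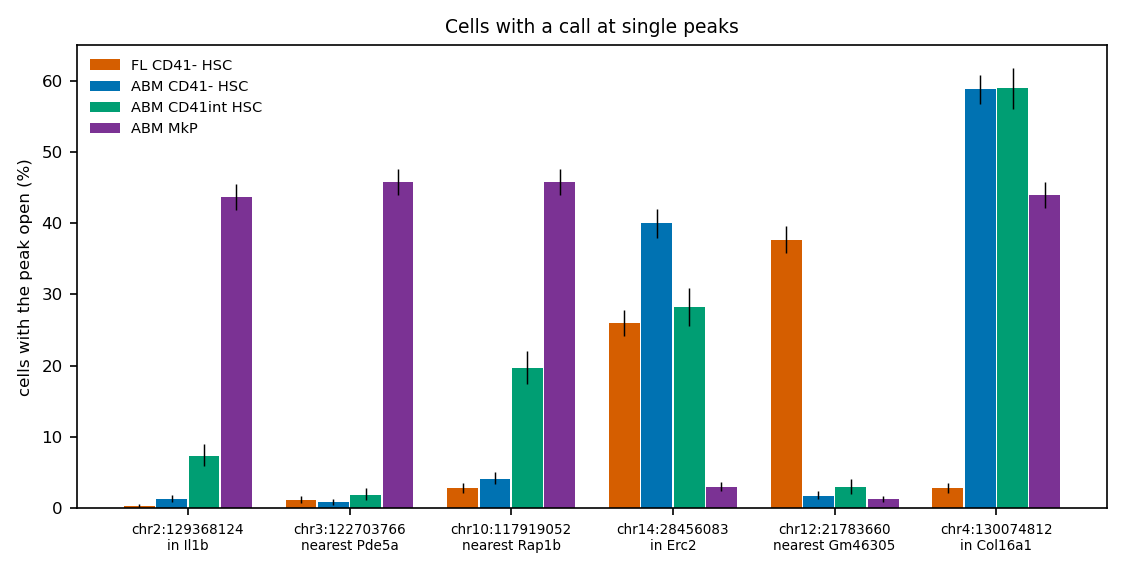
Percentage of cells with a call at 6 of the named peaks, by start coordinate and the gene they lie in or nearest to; bars are the 4 libraries and lines exact 95% intervals. Peaks in Il1b and near Pde5a and Rap1b are open in 43.7 to 45.8% of MkP cells, and the peak in Col16a1 in 2.83% of FL HSC.

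Chromatin that differed between the sorted MkP library and the HSC libraries was then measured without reference to genes. There were 8687 MkP-high and 7085 HSC-high peaks, and the MkP-high peaks were not confined to megakaryocyte genes, as given below. MkP-high peaks took 1.64% of open calls in FL CD41- HSC, 1.97% in ABM CD41- HSC, 2.66% in ABM CD41int HSC and 7.36% in MkP. Relative to ABM CD41- HSC the folds were 0.833 (0.829 to 0.837) for FL, 1.36 (1.35 to 1.36) for CD41int and 3.75 (3.73 to 3.76) for MkP. These intervals treat calls as independent and leave out differences between cells. The 5 other random splits gave FL folds of 0.839 to 0.850, outside the FL interval, and CD41int folds of 1.33 to 1.40. MkP-high peaks lay in the windows of 14 of 32 megakaryocyte genes, including Gp6, Gp1bb and Treml1 (median of random lists 8), of 11 of 19 erythroid (4), 7 of 12 endothelial (4) and 3 of 6 mast cell and basophil genes (1), and of 1 of 23 stem cell genes, Meis1 (7). Of the 14, Itgb3, Vwf, P2ry12 and Tbxas1 also held HSC-high peaks. HSC-high peaks took 5.54% of calls in FL HSC and 4.89% in ABM CD41- HSC, a fold of 1.13 that turned to 0.873 with peaks defined against ABM CD41- HSC alone and was 0.878 against CD41int HSC alone and 1.55 against FL HSC alone.

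The FL fold depended on the library that defined the peaks. It was 0.978 with MkP-high peaks defined against ABM CD41- HSC alone, 0.555 against FL HSC alone, and, in alternatives chosen after the data were seen, 1.02 against CD41int HSC alone and 0.894 against each of the 3 HSC libraries. The CD41int fold was above 1 in each of these definitions, but without the cells of MkP-dominated clusters and cluster 9, left out after the data were seen, it was 1.12; 818 of 1123 CD41int HSC remained. Peak by peak, 55.7% of MkP-high peaks were lower in FL than in ABM CD41- HSC, with a median log2 ratio of -0.06, and 80.5% were higher in CD41int HSC, with a median of 0.26.

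In MkP-high share, cells differed within the adult HSC libraries more than within the fetal one. Between the 10th and the 90th percentile of cells, the MkP-high share ran from 1.25 to 2.0% in FL HSC, from 1.15 to 3.03% in ABM CD41- HSC, from 1.33 to 4.32% in CD41int HSC and from 5.51 to 8.95% in MkP. The share of cells at or above the 5th percentile of MkP cells (4.94%) was 0.166% in FL (0.0202 to 0.60%), 0.952% in ABM CD41- (0.476 to 1.70%) and 6.23% in CD41int HSC (4.38 to 8.56%); this level marks a range of values and not a cell type, and the FL and ABM CD41- intervals overlapped. In the 4 other definitions of the peaks, tried for single cells after the data were seen, FL HSC kept the lowest share, with 0 to 3 of 1202 cells, against 0.952 to 2.68% of ABM CD41- and 4.63 to 15.7% of CD41int HSC, and the narrowest range between the 10th and the 90th percentile among HSC. The median cell, in contrast, was higher in FL than in ABM CD41- HSC with peaks defined against ABM CD41- HSC alone (1.92 against 1.81%) or CD41int HSC alone (1.35 against 1.22%). Between 4.75 and 5% lay 0 FL, 4 ABM CD41-, 9 CD41int and 12 MkP cells.

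**Figure D3:**
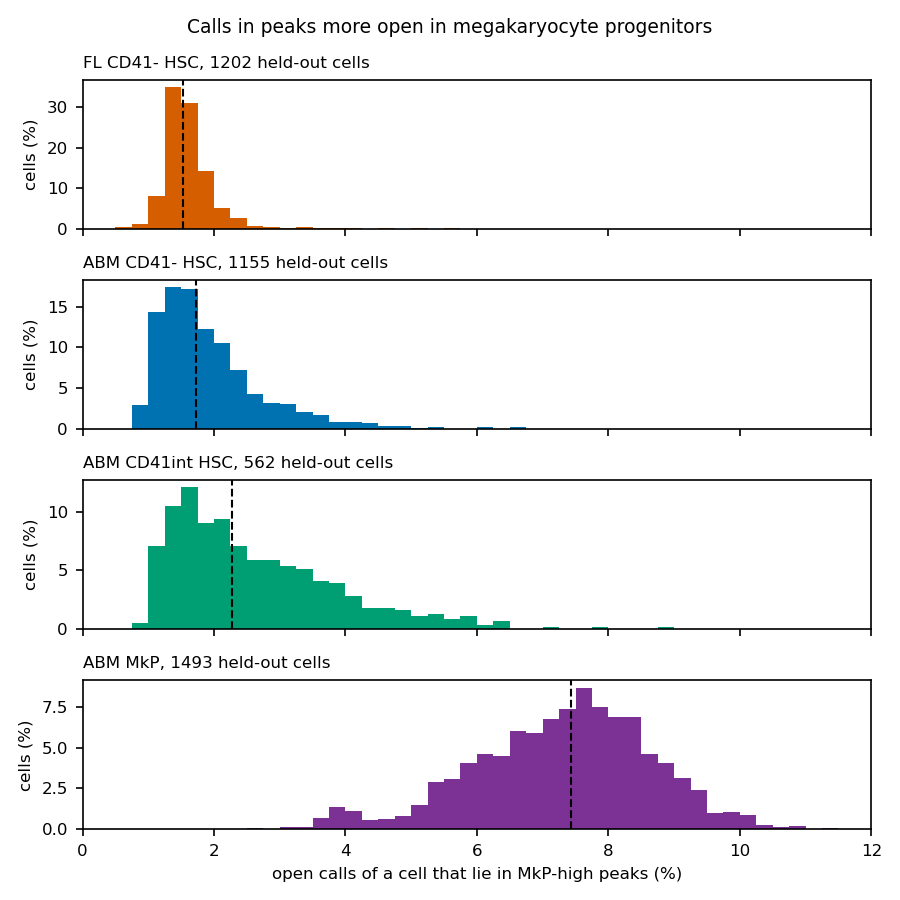
Share of each cell's open calls in MkP-high peaks (x axis, percent) against the percentage of held-out cells (y axis, scaled separately in each panel) for the 4 libraries; dashed lines are medians. The medians are 1.53% in FL CD41-, 1.72% in ABM CD41-, 2.28% in ABM CD41int and 7.43% in MkP cells, and the adult HSC libraries have a tail to the right.

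Clustering of all cells gave 11 clusters. FL HSC fell almost wholly in clusters 1 and 7, which held no adult cell (1601 and 764 cells), so these clusters may be the library as much as a cell state. Clusters 2, 5, 8, 10 and 11 were MkP-dominated and held 1.58% of FL (1.12 to 2.16%), 1.86% of ABM CD41- (1.35 to 2.5%) and 9.26% of CD41int HSC (7.63 to 11.1%). In clusters 2, 5 and 8, which had 5, 11 and 9 members of the megakaryocyte list at or above 0.5, more than of any other marker list, though this list is the longest, there were 0 of 2403 FL HSC, which allows a share of up to 0.125%, 9 of 2310 ABM CD41- HSC (0.390%, 0.178 to 0.738%) and 87 of 1123 CD41int HSC (7.75%, 6.25 to 9.47%). By median, the mast cell and basophil list led cluster 8 (0.51, 3 of 6 genes at or above 0.5, against 0.28 for megakaryocyte genes) and the macrophage list cluster 2 (0.37 against 0.27), and the 10 leading genes of these clusters held Cpa3 or Gzmb and no megakaryocyte list gene, so they are given by number. With 41754 peaks that were over 1.5-fold apart between FL and ABM CD41- HSC left out of the clustering, the shares in such clusters were 0.0416%, 0.519% and 7.93%.

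Cluster 10 was erythroid-like, with 13 erythroid genes at or above 0.5, Car1 and Kel leading, and cluster 11 had 10 granulocyte and monocyte genes, among them Mpo and Csf1r, and 8 lymphoid genes. They held 7.70% and 4.59% of MkP cells, 0.416% and 1.17% of FL HSC, and 0.303% and 1.17% of ABM CD41- HSC. Cluster 9 held 201 CD41int HSC (17.9%), 60 ABM CD41- HSC (2.60%), 14 MkP cells and no FL HSC, and Timd4 was among its leading genes. The macrophage list led this cluster, with Timd4 and C1qc at or above 0.5. Its median there was 0.21, against 0.06 for megakaryocyte genes.

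**Figure D4:**
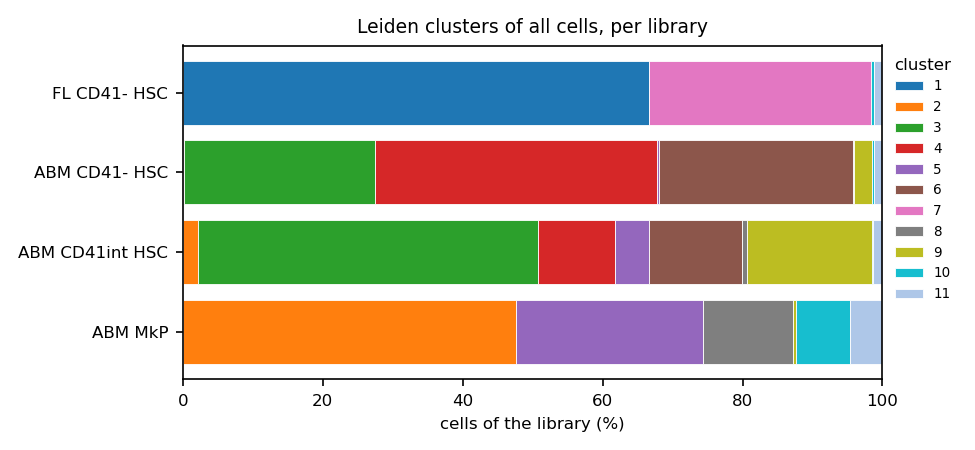
Percentage of each library's cells in each of the 11 clusters (colours). FL CD41- HSC lie mostly in clusters 1 and 7, and 7.75% of ABM CD41int HSC lie in clusters 2, 5 and 8, which hold most MkP cells.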

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

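Both tests of the mitochondrial pattern below were chosen after its values had been seen. Signal was found in peaks that no comparison used, on the mitochondrial genome and on chromosome Y.

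Of the cells, 81.3% in the ABM CD41- HSC library, 80.4% in the ABM CD41int HSC library and 82.9% in the MkP library had a call in at least 1 of 5 mitochondrial peaks. None of the 2403 FL CD41- HSC did, so 0 FL cells had such a call, although the FL library was the second largest in open calls. Less mitochondrial DNA in FL nuclei was argued against, since the lowest adult rate was 1569-fold above the FL limit of 3 calls, but the bound of 1000 set for that test was chosen after the 0 was known. Whether mitochondrial alignments were left out of the FL library before the matrix was made stays open, since its only test, the count of 0 FL cells, was the observation itself. If the FL library was processed apart, every FL over ABM ratio could be affected, which was not tested.

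Single-copy chromosome Y peaks, 13 in number, had a call in 51.8% of FL CD41- HSC and 49.0% of ABM CD41- HSC (46.9 to 51.1%). The shares were 36.2% of ABM CD41int HSC (33.4 to 39.1%) and 40.5% of MkP cells (38.7 to 42.2%). The labels do not give the sex of the animals. A different mix of sexes between libraries was not tested and stays possible in every comparison.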

How the results depend on the processing

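Gene windows of ends only or 10 kb, MkP-high definitions against CD41int HSC or each HSC library or near gene ends, clustering without FL and ABM CD41- differing peaks, all settings of clusters 2, 5 and 8, separate control cells, single cells under other MkP-high definitions, and removal of cells of MkP-dominated clusters and cluster 9 were tests chosen after the data were seen. No paired analysis was possible because each group was 1 library. Promoter windows, promoter peaks and motif shares were not run. An alternative was called the same when inside the counting interval of the main median, fold or share, or within 1.5-fold of a count. Reversed ones changed direction. Of 228 alternatives of the main values, 161 were the same, 66 moved and 1 reversed. Of 2644 for single genes, other lists, shared peaks and single cells, 2113 were the same, 520 moved and 11 reversed. The megakaryocyte list median kept its sign throughout, from -0.23 to -0.14 (FL over ABM CD41- HSC), 0.04 to 0.13 (CD41int), 0.19 to 0.29 (MkP) and -0.34 to -0.17 (FL over CD41int). Calls of 0 or 1 limit the most open peaks, and rare peaks rest on few cells.

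With gene ends only, the megakaryocyte median was 0.13 in CD41int HSC and 0.19 in MkP. The same setting reversed the lymphoid median in FL (-0.021) and in MkP (-0.054), the endothelial median in CD41int HSC (-0.0100), the mast cell and basophil median in MkP (-0.078), the stem cell median of FL over CD41int HSC (0.068), Cd163 in FL (0.21) and Alas2 in MkP (-0.24). With 10 kb windows the megakaryocyte median was -0.14 in FL, with 1 member at or below -0.5, and -0.17 for FL over CD41int HSC; Slc4a1 in FL (-0.32) and the mast cell and basophil median in MkP (-0.051) reversed. The latter was -0.061 with no minimum of calls. Thinning turned the lymphoid median of FL over CD41int HSC to -0.00080. The cause of these reversals was not tested.

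Counts of peaks moved with the thresholds by construction. Open in at least 2% of cells, 7208 peaks were higher in FL and 22 lower in CD41int HSC. At 10% there were 1642 higher and 2708 lower in FL, 139 and 6 in CD41int HSC, and 5146 and 3675 in MkP. At 1.5-fold these pairs were 11383 and 9708, 2227 and 639, and 15380 and 15166. At 4-fold they were 273 and 558, 0 and 0, and 1722 and 475. A pseudocount of 0.1 gave 7138 higher in FL, and 786 higher and 112 lower in CD41int HSC. Thinning and depth matching change depth and not a threshold. Thinning gave 2203 higher in FL, against 4468 in the main setting, and 5809 higher in MkP. Depth matching gave 28 lower in CD41int HSC.

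The MkP-high fold over ABM CD41- HSC, of FL and then CD41int, was 0.978 and 1.39 for peaks defined against ABM CD41- HSC alone, 0.555 and 1.23 against FL HSC alone, 1.02 (a reversal) and 1.27 against CD41int HSC alone, and 0.894 and 1.37 against each HSC library. It was 0.882 and 1.60 at 4-fold, 0.825 and 1.29 within 1 kb of gene ends, and 0.878 and 1.12 without cells of MkP-dominated clusters and cluster 9. The 5 other splits gave FL 0.850, 0.842, 0.842, 0.839 and 0.850, and 3 of them CD41int 1.38, 1.40 and 1.33. Depth matching gave FL 0.819 and thinning 0.805.

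Shares of MkP-dominated clusters at resolution 2 were 0.541% (FL) and 5.88% (CD41int), and thinned 0.437% (FL), 1.16% (ABM CD41-) and 6.19% (CD41int). With 15 components CD41int was at 11.3%. For clusters 2, 5 and 8, or those the same rule chose, CD41int was at 3.74% at resolution 2, 9.80% with 15 components, 6.14% with 50 and 5.55% thinned. By highest list median only cluster 5 was left, with 0.173% of ABM CD41- and 4.90% of CD41int HSC. The cause of these moves was not tested.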

Other observations

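The tests of MkP-like cells among ABM CD41- HSC and of a few FL cells of another kind were chosen after the results were seen. Outside the lists, the 183 immunoglobulin heavy chain variable genes (chromosome 12, 113572929 to 116009954) had 7.93 open calls per cell in MkP over 155 peaks, against 2.55 in ABM CD41- HSC, 2.32 in CD41int HSC and 1.09 in FL HSC. The rate in MkP was 2.85-fold that of ABM CD41- HSC (2.77 to 2.94), and that in FL 0.405-fold (0.387 to 0.424). The middle MkP cell had 7 such calls and the 10th percentile 2, so the signal was spread over most MkP cells. The region was singled out after its values were seen.

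Lower MkP-high signal in FL than in ABM CD41- HSC (0.833-fold, 0.829 to 0.837) was weighed first. For the run of FL ratios with openness, 1000 sets of other peaks matched on openness gave folds of 1.07 to 1.11. Openness thus came with no lower FL signal in these sets. MkP-high peaks, however, were chosen with FL among the references, and the matched sets were not. Peaks open enough in FL alone could also enter them. The test therefore cannot separate openness from the choice of peaks. Whether a few MkP-like cells in the ABM CD41- library account for it was not settled. The test kept the peaks chosen with FL among the references, so it cannot tell such cells apart from that choice. Without cells of MkP-dominated clusters and cluster 9 the fold was 0.878 (0.874 to 0.882), an interval that leaves out differences between cells. The library that defined the peaks could account for the lower FL signal, since the fold was 1.02 against CD41int HSC alone. Age, organ and the CD11b gate cannot be told apart in this design and remain open and untested.

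Peaks higher in FL and over 1 kb from gene ends, of which 4209 were chosen on 1 part of the cells, were weighed next. Even background in the FL library was not settled by its test. In cells not used to choose these peaks, their median excess was 5.86 percentage points. That was 12.1 times the excess of peaks open in under 2% of ABM CD41- HSC. The rule that chose the peaks already asked for a large excess, so the test could only speak against counting noise. A few FL cells of another kind were argued against, since 99.8% of held-out FL cells lay above the 95th percentile of ABM CD41- HSC. A copy number or mapping difference over chromosome 12, 17 to 24 Mb, where the 5 highest peaks lay, was argued against only as one that moves the whole region, since 78 peaks there that were open in ABM CD41- HSC had a median log2 ratio of 0.0036. Peaks there that were open only in FL HSC could not enter that test. Of 102 peaks there open in at least 5% of FL HSC, 21 had a log2 ratio of at least 1. Mapping at single peaks, library preparation, the CD11b gate, and age together with organ were not tested and stay open.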
